A study of Mus musculus with 14 samples.

How the data were processed

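The series holds 14 mouse samples in 2 phases. The table used here covers the 8 libraries of the first phase, 4 named D and 4 named M. The columns were matched to samples by their names: D is the initial of the diabetic group, and M was matched to the healthy group by elimination because no label explains it. The 3 diabetic-trained and 3 untrained samples of the second phase were not analysed here, so the comparison of those groups and the difference between phases were not made.

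Per the labels' design text, polyadenylated RNA was captured with oligo(dT), libraries were sequenced as DNA nanoballs, and reads were filtered with SOAPnuke 1.5.6 and aligned to mm10 with a program written as HISTA2 2.1.0. The same text names Ericscript 0.5.5, rMATS 3.2.5 and limma 3.66.0 with an unadjusted threshold of 0.05. The submitters' processing notes also name GRCm38. The quantifier and the annotation release are not given in the sources used here, nor is whether the counting used strand. Per the file headers and the values, the authors deposited estimated counts per RefSeq transcript, not normalized and 37.3% to 40.8% of them exactly whole, with no tolerance. The authors' TPM values are scaled by transcript length to the same total in each library. The authors' FPKM values are scaled by transcript length and library size, per the file headers. A further deposited signal, the authors' normalized counts, equalled the estimated counts rounded up and divided by one factor per library (0.953 to 1.063), within 0.001 for 100% of values. It was used only for this check, and 8 deposited columns of group means were not used.

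The table held 60072 transcripts of 17890 NCBI genes, of which 17836 had a symbol in the RefSeq gene table of GRCm38, the build whose coordinates are printed. Curated transcripts (NM) took 80.4% and predicted ones (XM) 19.6% of the counts, and 99.5% of counts fell on protein-coding genes. Second entries of 1575 transcripts took 1.41% and were summed with the rest. Estimated counts were summed per gene and rounded to whole numbers. Totals ran from 19048249 to 20028112 per library, the genes with a count from 15448 to 15895. Genes without enough counts were left out with edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), which left 12839. Mitochondrially encoded genes were not in the table, so that list was not tested.

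The main test was edgeR 4.0.16's quasi-likelihood test (TMM factors, robust fit, group only) with Benjamini-Hochberg adjustment and a threshold of 0.05, in R 4.3.3. TMM factors were 0.913 to 1.01 in the D and 1.03 to 1.05 in the M libraries. The biological coefficient of variation was 12.4%. Correlations of log2 CPM were 0.977 to 0.992 within and 0.946 to 0.977 between groups. Each pair of replicates differed by more than sampling noise (chi-square per gene 6.49 to 66.3), so no library was counted as a copy of another. CPM values use the TMM-scaled library sizes and are given as mean ± SD over 4 libraries; log2 fold changes are given ± SE.

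The 44 gene lists, the rule for named genes, the test and most alternatives were fixed before the data were examined. Lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry. Genes were named by rule: Acsl1 and Runx1; the 10 largest increases and 10 largest decreases among called genes whose groups did not overlap and whose mean log2 CPM was at least 1; up to 4 members with the lowest p from each list past camera and from 6 further lists of lipid, inflammatory and osteoclast genes; and up to 4 called members of other lists. The second part was drawn from 1751 higher and 1750 lower genes, and left out 76 gene models without a proper symbol. The rule named 110 genes, and 20 more were named after their values were seen. A further 15 lists of cell stages were written after the main results had been seen.

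The labels number the replicates 1 to 4 in both groups. Deviations from the group means of same-numbered D and M libraries correlated at 0.115, 0.131, 0.119 and 0.182, each above 0.1. Those of other pairs correlated at -0.178 to 0.0735. These values are small and tied together by the centring on group means, so the numbers may pair the samples but this is not settled. No label says what a number stands for. A fit with the number as a block was run as an alternative. Alternatives covered DESeq2 1.42.0 size factors and its test, upper-quartile factors, no filter (at least 1 count) and a filter of 50 counts, voom with and without quality weights, limma-trend on log2 FPKM or TPM (minimum 1; pseudocounts 1, 0.1 and 0.01), protein-coding genes only, the most abundant transcript per gene, other thresholds, and each library left out. Added after the data were seen were library totals only, voom with unadjusted p, and a fit without D replicates 1 and 3.

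The scripts were tested on simulated counts of the same 12839 genes, 4 against 4, with 200 genes changed. Of 50 genes per size, 30 were recovered at 1.5-fold, 45 at 2-fold, 50 at 4-fold and 49 at 8-fold, and 4.21% of calls were unchanged genes. A simulated list of 37 genes shifted by 0.5 on the log2 scale passed camera with an estimated correlation (adjusted p = 0.00032), and 2 lists passed at the preset correlation. The simulated genes were drawn independently, whereas the real lists past camera had estimated correlations of 0.047 to 0.75. The simulation therefore does not show how the list tests or the share of false calls behave with correlated genes. It also changed far fewer genes than the 4456 called in the data. Adjustment is stricter when fewer genes change, so its recovery and share of false calls do not carry over to these data. Genes with near-identical copies share reads, and how the deposited counts split them is not known. Without a stated use of strand, reads of overlapping genes cannot be told apart; Ifit3b, Ifit1, Gpat3, Slc16a3, Ccna2, Rpl19 and Cd72 overlap another tested gene.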

Results

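Messenger RNA was sequenced from what the labels name bone marrow-derived macrophages, cells grown from bone marrow progenitors with the macrophage growth factor M-CSF. The donors were male C57BL/6J mice, an inbred laboratory strain, 8 weeks old at the start. Diabetes was induced with streptozotocin, a toxin of insulin-producing beta cells, at 42 to 45 mg/kg a day for 5 days, and a blood glucose above 16.9 mmol/L counted as diabetic. After 6 weeks of hyperglycaemia, progenitors of both groups were cultured for 7 days in medium with 5 mmol/L glucose. The table analysed here holds 4 libraries whose names carry a D and 4 whose names carry an M. D is the initial of diabetic. No label explains M, which was matched to the healthy mice by elimination, so every direction is given as D relative to M and would turn if the letters meant the opposite. The 8 libraries held 19048249 to 20028112 estimated counts each. The labels do not say that each library came from its own animal, so the p-values measure the spread between these samples, which may be technical. The second phase of the study, 3 diabetic-trained and 3 untrained samples, was not analysed here.

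The D and M libraries were compared to ask which transcripts differ in cultures labelled as macrophages from the marrow of diabetic mice once glucose is equal. Acsl1 is named in the series title. Cd79b, a chain of the B-cell receptor complex, was lower in the D libraries, at 28.7 ± 11.3 CPM (SD, n = 4) against 277 ± 43.5 CPM in the M libraries. The interferon-induced antiviral gene Ifit3 was higher, at 42.3 ± 31.5 against 4.34 ± 2.13 CPM. Its level was 87.3 CPM in D replicate 4 and 20.4 to 41.1 CPM in D replicates 1 to 3. Fcer1a, the IgE receptor chain of mast cells and basophils, was higher too, at 30.8 ± 4.54 against 6.74 ± 0.940 CPM. Acsl1, an enzyme that joins long-chain fatty acids to coenzyme A, was 1.26-fold higher, at 168 ± 23.4 against 134 ± 6.81 CPM.

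Of 12839 genes tested, 2233 were higher and 2223 lower in the D libraries, 34.7% in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at a threshold of 0.05. Most changes were small: the median absolute log2 fold change of the called genes was 0.48, and 295 higher and 503 lower genes reached 2-fold. In 4452 tested genes (34.7%) every library of one group lay above every library of the other, where chance gives 2.86%. The first principal component took 64.7% of the variance and separated the groups, with D replicate 1 at -16.0, D replicate 3 at -54.5 and the M libraries between 27.9 and 37.6. Without both of those D libraries, an alternative chosen after the data were seen, 2389 genes were higher and 1970 lower. The split between directions depended on the scaling. With TMM factors 50.1% of called genes were higher in the D libraries, against 30.9% to 31.1% with the deposited FPKM, 33.0% to 33.2% with TPM and 31.3% with library totals alone, which moved the median of all genes by -0.10 to -0.11, -0.09 and -0.10 on the log2 scale. Taking only the most abundant transcript of each gene left 2053 genes called.

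**Figure D1:**
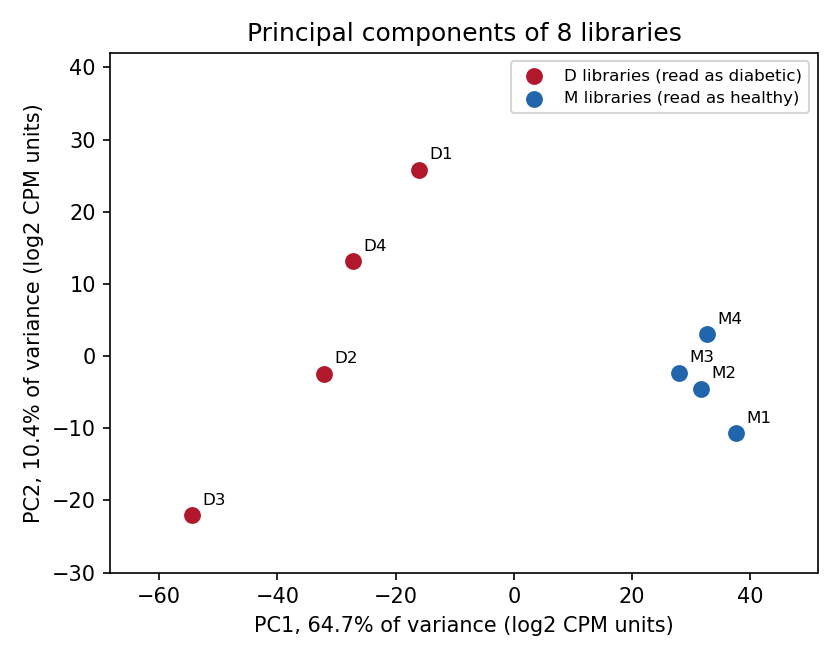
Position of the 8 libraries on the first principal component (64.7% of the variance, x axis) and the second (10.4%, y axis) of log2 CPM, with one point per library. The 4 D libraries lie from -54.5 to -16.0 on the x axis and the 4 M libraries from 27.9 to 37.6.

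Acsl1 (NCBI gene 14081, chromosome 8, 46471037 to 46536051, build GRCm38) had a log2 fold change of 0.33 ± 0.09 (SE, n = 4 per group; adjusted p = 0.0196). Its level was 157, 148, 202 and 167 CPM in D replicates 1 to 4 and 133, 142, 126 and 134 CPM in M replicates 1 to 4, so each D library lay above each M library. The study may have chosen Acsl1 on these samples, so its direction is not independent evidence. The call ended without M replicate 3 (0.31, adjusted p = 0.0569) and with the deposited FPKM (0.22, adjusted p = 0.0500 to 0.0504), while the adjusted p over the other alternatives lay between 0.00377 and 0.0484. With the most abundant transcript alone the log2 fold change was 0.52 (adjusted p = 0.0248). Runx1 (NCBI gene 12394, chromosome 16, 92601466 to 92826074), a transcription factor of blood cell development, stood at 97.2 ± 5.94 against 90.7 ± 6.13 CPM and did not pass (log2 fold change 0.10 ± 0.07, adjusted p = 0.307). Its sign turned with FPKM and with library totals.

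Genes of fatty acid synthesis did not pass as a group (median log2 fold change 0.11, camera adjusted p = 0.210). Of 25 tested members 5 were higher and 0 lower, a smaller share than the 34.7% called over all tested genes. Adjusted over the list alone 4 were higher. The 5 were Acsl1, the elongases Elovl7 (19.6 ± 4.82 against 9.93 ± 1.94 CPM) and Elovl5 (137 ± 15.4 against 110 ± 2.07 CPM), the arachidonate-preferring Acsl4 (99.6 ± 13.3 against 79.6 ± 4.25 CPM) and the desaturase Scd2 (827 ± 419 against 385 ± 46.3 CPM). Without D replicate 4 the group passed (median 0.20, adjusted p = 0.0162), but over all libraries it was far from passing with an estimated correlation (adjusted p = 0.894). Among 10 long-chain acyl-CoA synthetases 4 were higher and 1 lower, 6 and 2 adjusted over the list alone, and the group did not pass (adjusted p = 0.568). The higher members besides Acsl1 and Acsl4 were the transporter Slc27a4 (270 ± 34.2 against 207 ± 11.8 CPM) and Acsbg1 (2.53 ± 1.10 against 1.19 ± 0.449 CPM), and the lower was the mitochondrial Acsf2 (10.8 ± 1.53 against 19.3 ± 0.969 CPM). Scd2 and Acsbg1 were named after their values were seen. Both calls ended without D replicate 2 or 3 or any 1 M library, at an adjusted p up to 0.0852 and 0.117. The call of Acsl4 ended without D replicate 2, M replicate 1 or M replicate 4 (adjusted p = 0.0607 to 0.0629), with FPKM and TPM (log2 fold change 0.20 to 0.22, adjusted p = 0.0797 to 0.0811) and with library totals (0.21, adjusted p = 0.0640), and its direction turned with the most abundant transcript alone. That last setting also ended the calls of Elovl5 (0.23, adjusted p = 0.317), Elovl7 (1.13, adjusted p = 0.0910) and Scd2 (1.09, adjusted p = 0.0619), and FPKM that of Elovl5 (0.20, adjusted p = 0.0549 to 0.0553). With TPM the calls of Scd2 (0.87, adjusted p = 0.0551 to 0.0620) and Acsbg1 (0.50 to 0.95, adjusted p = 0.0776 to 0.0820) ended. That of Scd2 also ended with no filter (adjusted p = 0.0764), with FPKM at pseudocounts 0.1 and 0.01 (adjusted p = 0.0521 and 0.0544) and without both end libraries of the D group (adjusted p = 0.0785). That of Acsbg1 also ended with voom (adjusted p = 0.0503), voom with quality weights (adjusted p = 0.0530), library totals (adjusted p = 0.0551) and without both end libraries (adjusted p = 0.0653).

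Genes of fatty acid oxidation had a median of -0.09 over 27 members, of which 2 were higher and 4 lower. Adjusted over the list alone, 0 were higher and 3 lower. This list did not pass camera (adjusted p = 0.546, or 0.894 with an estimated correlation) but did pass fry (adjusted p = 0.0287).

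Lipid storage and transport genes went both ways, and the shares that passed lay near the 34.7% of all tested genes. In the list of lipid droplets and triglyceride metabolism 7 of 20 tested members passed (6 higher and 3 lower adjusted over the list alone), with a median of 0.08 and an adjusted p of 0.490. Dgat1, which makes triglyceride, was 1.66-fold higher (156 ± 21.1 against 94.4 ± 9.64 CPM) and the acyltransferase Agpat2 was 1.31-fold higher, while the acyltransferases Agpat3 (8.25 ± 1.69 against 17.2 ± 1.43 CPM) and Gpat3 (34.8 ± 2.35 against 45.6 ± 2.33 CPM) were lower. Gpat3 overlaps another tested gene and turned with its most abundant transcript. In the list of lipid uptake and efflux 7 of 22 passed (5 higher and 2 lower adjusted over the list alone), with a median of 0.03 and an adjusted p of 0.582. The cholesterol exporters Abca1 (10.1 ± 4.34 against 2.79 ± 0.389 CPM) and Abcg1 (36.0 ± 16.0 against 10.7 ± 1.97 CPM) were higher. The fatty acid receptor Cd36 was lower (16.3 ± 5.32 against 41.7 ± 13.5 CPM), and so was the lipid carrier Apoe (41.8 ± 3.58 against 55.1 ± 8.54 CPM; adjusted p = 0.0522 without D replicate 2). With the most abundant transcript alone Cd36 was at -0.60 (adjusted p = 0.341), and the calls of Abca1 (2.64, adjusted p = 0.309) and Apoe (-0.43, adjusted p = 0.116) ended with log2 fold changes no smaller than before. In the same libraries the 22 neutrophil markers had a median log2 fold change of 0.53.

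**Figure D2:**
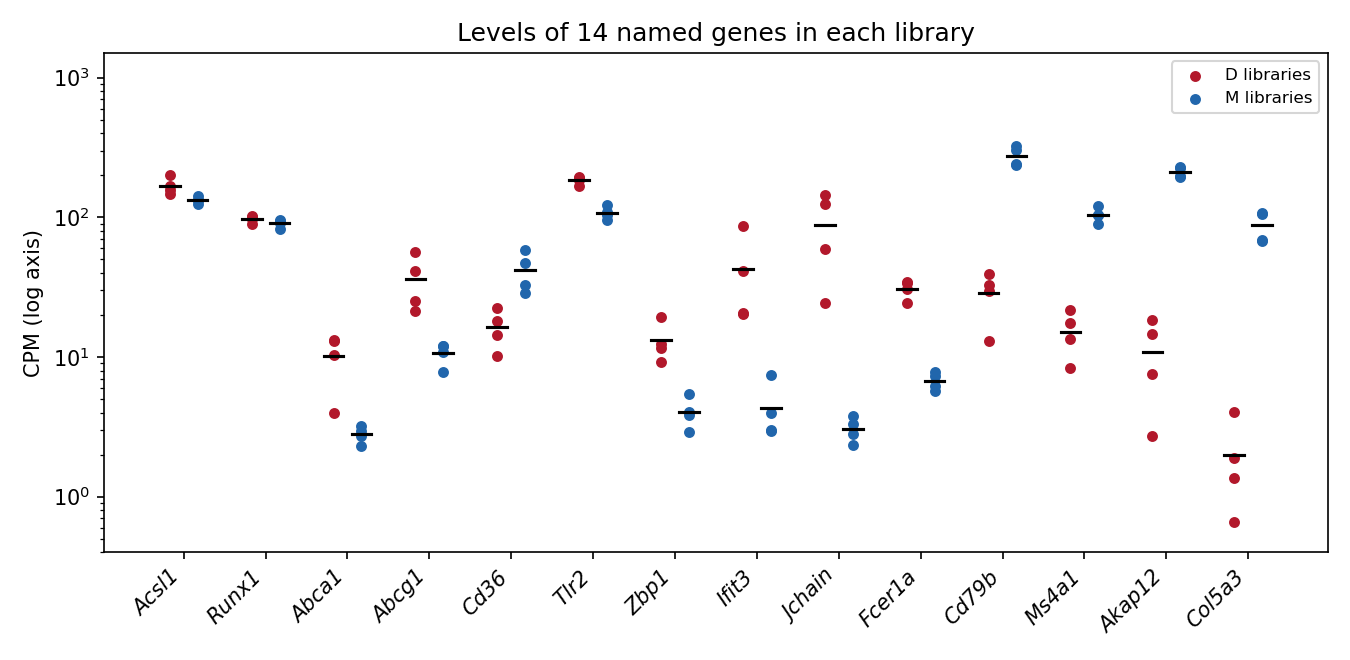
Level of 14 named genes in CPM (log axis), with one point per library and a bar at the mean of each group of 4. Acsl1 lies between 148 and 202 CPM in the D libraries and between 126 and 142 CPM in the M libraries.

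The largest increases among genes whose groups did not overlap were led by Jchain (NCBI gene 16069, chromosome 5, 88519809 to 88527897), the joining chain of secreted IgM and IgA, with a log2 fold change of 4.84 ± 0.61 (87.8 ± 55.7 against 3.06 ± 0.626 CPM; adjusted p = 0.000852). Interferon-induced genes followed, Ifit3b at 3.71, Ifit3 at 3.29, Ifit1 at 3.09 and the GTPase Tgtp1 at 2.96. The remaining 5 were the neutrophil chemokine receptor Cxcr1 (3.13), the natural killer receptor Klrc1 (2.82), fibronectin (Fn1, 2.61; 77.8 ± 48.6 against 12.7 ± 3.90 CPM), Sirpb1c (2.46) and the monocyte chemokine Ccl7 (2.31). The largest decreases were led by Col5a3 (NCBI gene 53867, chromosome 9, 20770050 to 20815117), a chain of type V collagen, at -5.44 ± 0.41 (1.99 ± 1.47 against 87.5 ± 22.0 CPM; adjusted p = 7.97e-05). Irs1, the insulin receptor substrate, was at -4.74 (0.273 ± 0.222 against 7.49 ± 2.16 CPM) and Akap12, a scaffold of protein kinase A, at -4.28 (10.8 ± 7.06 against 211 ± 17.9 CPM). The other 7 were Lrrc10b, Myzap, Tmem132e, Nyx, Sertad4, the metalloprotease Adamts7 and the serine protease Prss23, at -4.87 to -4.01. B and plasma cell markers had a median of -2.83 in the same libraries. The lowest value in a list of pro-B and pre-B cell genes, written after the data were seen, was -4.28, that of Akap12 itself. That list therefore gives no separate evidence on Akap12. Whether the largest decreases, that of Irs1 included, arose in macrophages or in B-lineage cells was not tested. Ifit3 and Ifit3b, Tgtp1, Klrc1 and Sirpb1c have near-identical relatives, Ifit3b and Ifit1 overlap another tested gene, and reads split between such copies make their levels uncertain. The call of Klrc1 ended with the most abundant transcript alone (2.32, adjusted p = 0.356). Ifit1, Ifit3 and Ifit3b were highest in D replicate 4, at 73.8, 87.3 and 42.9 CPM. The other D libraries held 12.9 to 29.7, 20.4 to 41.1 and 9.31 to 24.9 CPM of them.

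Of the 32 tested interferon response genes 25 were higher in the D libraries and 0 lower, 26 and 0 adjusted over the list alone. The median log2 fold change was 1.15 (camera adjusted p = 4.8e-12; adjusted p = 0.568 with an estimated correlation). The RNA sensor Ifih1 was 2.23-fold, the nucleic acid sensor Zbp1 3.25-fold and the antiviral Ifit2 2.51-fold higher, and the call of Ifit2 ended with the most abundant transcript alone (log2 fold change 2.96, adjusted p = 0.0877). The late neutrophil genes of a list written after the data were seen were higher too, with a median of 0.92 over 14 genes.

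Of 19 complement and Fc receptor genes 13 were higher and 0 lower, 14 and 0 adjusted over the list alone (median 0.71; adjusted p = 2.3e-06; adjusted p = 0.440 with an estimated correlation). The high-affinity IgG receptor Fcgr1 stood at 21.9 ± 3.17 against 8.02 ± 1.62 CPM, and the anaphylatoxin receptor C5ar1 at 465 ± 93.4 against 274 ± 28.2 CPM. Properdin (Cfp) was 1.64-fold and C1qa 2.75-fold higher, the latter at only 2.00 ± 0.329 CPM in the D libraries. Toll-like receptors and adaptors had 16 of 27 members higher and 3 lower, 17 and 5 adjusted over the list alone (median 0.36; adjusted p = 0.00164; adjusted p = 0.840 with an estimated correlation; fry adjusted p = 0.0604, or 0.0367 with the replicate number as a block). Tlr2, a receptor of bacterial lipopeptides, was at 185 ± 12.4 against 108 ± 11.1 CPM and Nod1, a sensor of peptidoglycan, at 20.9 ± 4.01 against 12.2 ± 0.832 CPM. The lower members were the DNA receptor Tlr9 (10.6 ± 3.50 against 29.1 ± 3.59 CPM), the signalling ligase Traf6 (56.9 ± 3.59 against 77.9 ± 5.66 CPM) and the adaptor Ticam2 (19.3 ± 0.832 against 22.8 ± 1.50 CPM). Of 17 inflammasome genes 13 were higher and 1 lower, 13 and 2 adjusted over the list alone (median 0.37; adjusted p = 0.000502; adjusted p = 0.572 with an estimated correlation). Nlrp3, Casp1, Mefv and Gsdme were 1.49-fold, 1.26-fold, 1.56-fold and 1.83-fold higher. The cytokine Il1b, named after its values were seen, stood at 162 ± 73.5 against 47.4 ± 27.4 CPM, and its call ended without D replicate 2, D replicate 3 or M replicate 4 (adjusted p = 0.0574 to 0.0701) and with no filter (adjusted p = 0.0663). The lower member was Nlrc4 (8.79 ± 0.766 against 11.7 ± 1.97 CPM). The calls of Nlrc4 and Ticam2, both named after their values were seen, each ended without any of 6 libraries (the exceptions were D replicate 3 and M replicate 4 for Nlrc4, and D replicate 1 and M replicate 4 for Ticam2; adjusted p up to 0.0872 and 0.139), and that of Nlrc4 with the block (adjusted p = 0.0645) and voom with quality weights (adjusted p = 0.0548). That of Ticam2 also ended with DESeq2's size factors (adjusted p = 0.0556), its test (adjusted p = 0.0584) and no filter (adjusted p = 0.0641). Without both end libraries of the D group neither passed (adjusted p = 0.137 for Nlrc4 and 0.0647 for Ticam2). Calls that ended with the most abundant transcript alone were those of Nlrp3 (0.54, adjusted p = 0.0817), Ticam2 (-0.25, adjusted p = 0.0820) and Nlrc4 (-0.34, adjusted p = 0.899). Neutrophil markers had a median of 0.53 in the same libraries, and Il1b is also one of the late neutrophil genes (median 0.92).

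Markers of macrophage identity were higher in 11 of 24 members and lower in 1, both over all genes and adjusted over the list alone (median 0.31; adjusted p = 0.000479; adjusted p = 0.568 with an estimated correlation). Lysozyme (Lyz2) stood at 8145 ± 1911 against 4606 ± 303 CPM, the monocyte chemokine receptor Ccr2 at 215 ± 33.8 against 105 ± 16.2 CPM and the transcription factor Maf at 30.0 ± 3.65 against 14.9 ± 1.46 CPM. The lower member was the lectin Clec4n (19.4 ± 8.70 against 44.7 ± 20.9 CPM), named after its values were seen. Its call ended without D replicate 1, 3 or 4 or M replicate 1, 2 or 3, with an adjusted p up to 0.136, and with the most abundant transcript alone (-1.20, adjusted p = 0.0965). It also ended with DESeq2's size factors (adjusted p = 0.0511), no filter (adjusted p = 0.106), voom with quality weights (adjusted p = 0.0866) and without both end libraries of the D group (adjusted p = 0.284). Inflammatory cytokines and M1 markers went both ways: 15 of 22 members passed, 10 of them higher, with the same counts adjusted over the list alone (median 0.57; adjusted p = 0.210). The formyl peptide receptor Fpr2 (261 ± 51.8 against 132 ± 11.2 CPM) and the siderophore-binding Lcn2 (1868 ± 187 against 1262 ± 79.8 CPM) were higher. The ectoenzyme Cd38 (13.6 ± 3.09 against 51.6 ± 6.22 CPM) and Il12a (8.33 ± 2.38 against 19.5 ± 2.14 CPM), a subunit of interleukin 12, were lower. Lcn2 is also one of the neutrophil markers (median 0.53 in these libraries) and Fpr2 one of the late neutrophil genes (median 0.92). The M1 group passed with TPM (adjusted p = 0.0382) and without both end libraries of the D group (adjusted p = 0.0433), but over all libraries it did not with an estimated correlation (adjusted p = 0.894).

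Libraries of these cultures held many transcripts typical of other marrow cells. Macrophage identity markers summed to 22924 ± 2602 CPM in the D and 17862 ± 995 CPM in the M libraries, less than the neutrophil markers below. Such sums depend on the genes listed and do not measure shares of cells. Among the 20 most abundant genes were the neutrophil markers Ngp (0.585% of counts) and Ltf (0.307%). The macrophage markers Lyz2 (0.629%) and Mpeg1 (0.363%) were among them too. The labels name the cells macrophages, but these values do not show that macrophages made up most of the cultures. Differences between the groups are those of the whole culture and cannot be assigned to macrophages alone. The most abundant genes were S100a9 (1.67% of counts) and S100a8, the calprotectin subunits of neutrophils and monocytes, named after their values were seen. S100a8 was higher in the D libraries (12286 ± 2215 against 8996 ± 609 CPM), a call that ended without M replicate 2, 3 or 4 (adjusted p = 0.0532 to 0.0550) and with the most abundant transcript alone (0.44, adjusted p = 0.0538). S100a9 did not pass (18448 ± 3759 against 15195 ± 320 CPM; adjusted p = 0.126) but did without D replicate 1 (adjusted p = 0.0143), without both end libraries of the D group (adjusted p = 0.0325) and with voom and quality weights (adjusted p = 0.0442). Of 22 neutrophil markers 14 were higher and 0 lower, 15 and 0 adjusted over the list alone (median 0.53; adjusted p = 2.3e-06; adjusted p = 0.580 with an estimated correlation). Their summed level was 57464 ± 10255 CPM in the D and 41339 ± 970 CPM in the M libraries. The granule proteins Camp, Pglyrp1 and Ngp were 1.66-fold, 1.65-fold and 1.62-fold higher. Mast cell, basophil and eosinophil markers were higher in 11 of 15 members and lower in 0, 12 and 0 adjusted over the list alone (median 0.87; adjusted p = 5.6e-10; adjusted p = 0.0655 with an estimated correlation). Besides Fcer1a, the basophil proteases Prss34 (365 ± 61.3 against 139 ± 21.5 CPM) and Mcpt8 (202 ± 46.2 against 67.5 ± 11.1 CPM) and the eosinophil lectin Siglecf (1.82-fold) were higher.

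Lymphoid, dendritic and platelet markers moved apart. Of 14 B and plasma cell markers 11 were lower and 1 higher, over all genes and adjusted over the list alone (median -2.83; adjusted p = 3.2e-12; adjusted p = 0.543 with an estimated correlation). The CD20 gene Ms4a1 (15.2 ± 5.66 against 105 ± 12.9 CPM), Cd22 (12.3 ± 4.08 against 55.7 ± 6.71 CPM) and Mzb1 (7.13 ± 0.894 against 21.2 ± 2.14 CPM) were lower, and the higher member was Jchain. T and NK cell markers were higher in 8 of 16 members and lower in 2, 10 and 2 adjusted over the list alone (median 0.56; adjusted p = 0.00255; adjusted p = 0.568 with an estimated correlation). The summed level of the T and NK list was not higher, at 173 ± 18.1 CPM in the D against 191 ± 22.4 CPM in the M libraries. The T-cell receptor chains Cd3e and Cd3g were 2.43-fold and 2.25-fold higher and granzyme B (Gzmb) 3.74-fold, each with a mean under 10 CPM in the D libraries. The lower members were the interleukin 7 receptor Il7r (1.94-fold lower) and Cd2 (9.44 ± 1.91 against 15.2 ± 2.43 CPM), the latter named after its values were seen and not past the threshold without both end libraries of the D group (adjusted p = 0.0589). Dendritic cell markers were lower in 8 of 15 members and higher in 1, as they were adjusted over the list alone (median -0.49; adjusted p = 0.0128; adjusted p = 0.596 with an estimated correlation), a call that ended with TPM (median -0.70, adjusted p = 0.126). The transcription factors Irf4 (17.4 ± 5.37 against 118 ± 12.5 CPM) and Tcf4 (41.4 ± 5.07 against 58.2 ± 4.98 CPM), the plasmacytoid marker Siglech and the homing receptor Ccr7 were lower. Irf4 is also one of the plasma cell genes of a list written after the data were seen, so it does not mark dendritic cells alone. With the most abundant transcript alone Tcf4 was at -0.15 (adjusted p = 0.830), Irf4 at -2.01 (adjusted p = 0.164) and Siglech at -1.13 (adjusted p = 0.0619), and their calls ended. The higher member was Ffar2, a receptor of short-chain fatty acids (17.4 ± 1.63 against 13.7 ± 1.50 CPM). It was named after its values were seen, and its call ended without D replicate 2, M replicate 2 or M replicate 3 (adjusted p = 0.0576 to 0.0757), with the most abundant transcript alone (0.33, adjusted p = 0.291), with library totals (adjusted p = 0.0864) and without both end libraries of the D group (adjusted p = 0.0708). Erythroid and megakaryocyte markers were lower in 6 of 17 members and higher in 0, with the same counts adjusted over the list alone (median -0.71; adjusted p = 0.000479; adjusted p = 0.840 with an estimated correlation). The platelet genes Ppbp (21.0 ± 6.74 against 94.0 ± 18.8 CPM), Pf4, Gp9 and Itga2b were among them.

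**Figure D3:**
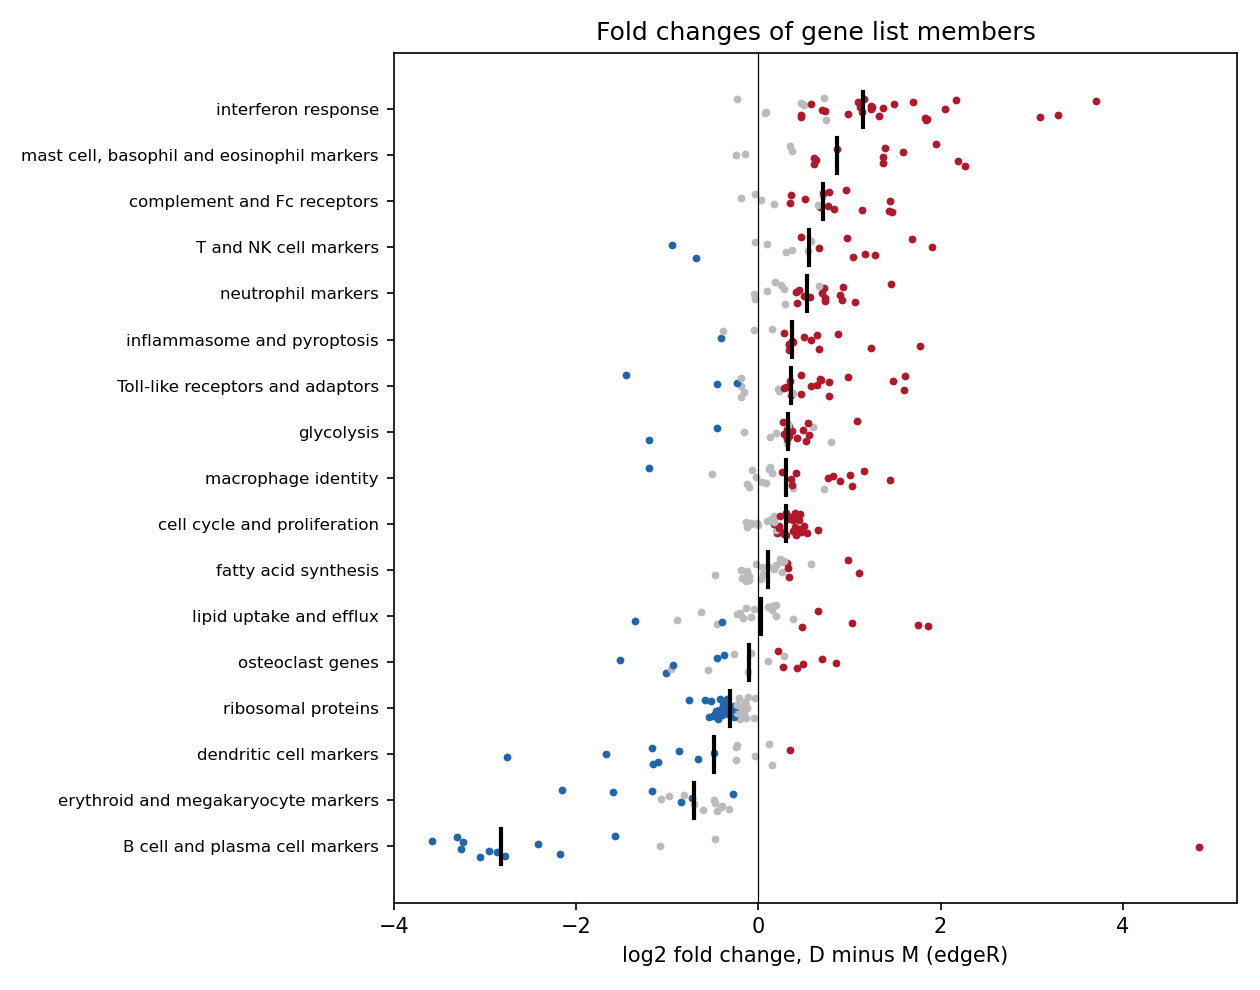
Log2 fold change of D relative to M for the tested members of the gene lists, with one point per gene and a mark at each list's median. The median was -2.83 for B and plasma cell markers and 1.15 for interferon response genes.

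Cell cycle genes were higher in 27 of 39 members and lower in 0, 29 and 0 adjusted over the list alone (median 0.30; adjusted p = 4.6e-07; adjusted p = 0.568 with an estimated correlation). Cyclin A2 (Ccna2, 166 ± 10.7 against 120 ± 6.30 CPM) and cyclin B1 (Ccnb1, 90.4 ± 4.95 against 67.9 ± 2.54 CPM), which drive S phase and mitosis, the ubiquitin-conjugating Ube2c and the centromere histone Cenpa were 1.32-fold to 1.39-fold higher. Ribosomal proteins were lower in 26 of 42 members and higher in 0, 30 lower and 0 higher adjusted over the list alone (median -0.31; adjusted p = 5.9e-07; adjusted p = 0.856 with an estimated correlation). Rplp2 (212 ± 26.2 against 358 ± 49.9 CPM), Rpl14, Rpl19 and Rpl35 were lower, and the many processed copies of such genes in the genome make single levels uncertain. Glycolysis genes were higher in 13 of 23 members and lower in 2, 16 and 2 adjusted over the list alone (median 0.33; adjusted p = 0.000507; adjusted p = 0.848 with an estimated correlation; fry adjusted p = 0.0604). The lactate exporter Slc16a3 (260 ± 80.9 against 123 ± 11.6 CPM), lactate dehydrogenase A (Ldha, 777 ± 96.2 against 527 ± 27.3 CPM), the regulator Pfkfb4 and Pgam1 were higher. The lower members, named after their values were seen, were the enolase Eno2 (1.16 ± 0.424 against 2.68 ± 1.05 CPM) and the lactate transporter Slc16a1 (87.6 ± 14.5 against 120 ± 9.22 CPM). The call of Eno2 ended without D replicate 4, M replicate 1 or M replicate 2 (adjusted p = 0.0551 to 0.0623). It ended too with the most abundant transcript alone (-0.85, adjusted p = 0.522), as did that of Pfkfb4 (0.47, adjusted p = 0.0561). B and plasma cell markers, at a median of -2.83, and neutrophil markers, at 0.53, moved in the same libraries as these groups.

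Osteoclast genes did not pass as a group (median -0.10; adjusted p = 0.546). Of 18 members 11 passed, 6 of them higher, and 6 were higher and 7 lower adjusted over the list alone. The bone-resorption phosphatase Acp5 (7.52 ± 0.938 against 15.2 ± 0.681 CPM), the integrin Itgb3 (81.5 ± 11.7 against 157 ± 19.7 CPM), the kinase Src (5.85 ± 1.58 against 16.8 ± 2.71 CPM) and Traf6 were lower. Of the higher members the matrix protease Mmp9, named after its values were seen and also a late neutrophil gene, stood at 2229 ± 519 against 1239 ± 91.1 CPM. The summed level of the list was 3335 ± 473 against 2518 ± 33.1 CPM, a smaller difference than that of Mmp9 alone. Without Mmp9 the sum would be lower in the D libraries. The call of Src ended with the most abundant transcript alone (-2.46, adjusted p = 0.211). Itgb3 is also a platelet integrin, and the erythroid and megakaryocyte markers had a median of -0.71 in these libraries.

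In all, 43 lists were tested and 14 passed camera with its preset correlation of 0.01, 10 of them higher and 4 lower in the D libraries; with an estimated correlation 0 passed, the smallest adjusted p being 0.0655. The self-contained test fry, which asks whether the members of a list move on balance one way and compares them with no other gene, passed 14 lists, 12 of them shared with camera. The others were fatty acid oxidation and the stromal, fibroblast and endothelial markers (median -0.51; camera adjusted p = 0.0794; fry adjusted p = 0.0287), which passed camera with the block (adjusted p = 0.00643) but not with the block and an estimated correlation (adjusted p = 0.570). With the most abundant transcript alone, 101 of the 130 named genes passed, against 128 with transcripts summed.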

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

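In this part no test was chosen after its result was seen, but Scd2, Nlrc4 and Clec4n are genes named after their values were seen. In 17 of 262 groups of 4 libraries, 1 library stood apart from the other 3 by Dixon's test of gap over range, and chance alone gives about 1 in 20 groups, or 13.1. No explanation was tested for any of them. D replicate 3, the library farthest out on the first principal component, accounted for 6: Myzap (0.221 CPM, others 0.302 to 0.313), Agpat3 (5.74, others 8.86 to 9.45), Acp5 (6.12, others 7.85 to 8.17), Tcf4 (33.8, others 43.6 to 44.3), Ccr7 (8.33, others 20.4 to 20.8) and Mzb1 (5.79, others 7.45 to 7.66). In each of these the level was the lowest of the D group. M replicate 1 stood apart in Ccr2 (81.0 CPM, others 112 to 115), Tcf4 (50.8, others 59.9 to 61.5) and Ngp (5220, others 4170 to 4340).

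M replicate 2 was lower than the other M libraries in Slc27a4 (189 CPM, others 211 to 215) and Lcn2 (1140, others 1280 to 1310). M replicate 3 was lower in Itga2b (139 CPM, others 172 to 177) and higher in Scd2 (454, others 354 to 368). D replicate 1 was higher than the other D libraries in Dnmt3a (56.8 CPM, others 47.6 to 48.0) and lower in Nlrc4 (7.65, others 9.09 to 9.22). D replicate 2 was higher in Clec4n (32.4 CPM, others 14 to 15.8), and D replicate 4 in Mtor (59.6, others 53 to 53.8).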

How the results depend on the processing

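Of the alternatives here, library totals alone, voom with an unadjusted p and the fit without both end libraries of the D group were chosen only after the results were seen. The count of changed genes, 4456 of 12839, ranged from 3458 to 5369 with 1 library left out, the genes higher from 1710 to 2865 and those lower from 1583 to 2504. With the most abundant transcript per gene 2053 genes were called, 1088 higher and 965 lower; 1913 of them were shared with the 4456 in the same direction and 2 in the opposite one. Requiring 2-fold left 798, with 295 higher and 503 lower, by construction. FPKM gave 1360, 1354 and 1353 genes higher with pseudocounts 1, 0.1 and 0.01, TPM 1456, 1450 and 1440, and library totals 3346 genes lower. These settings moved the genes by a median of -0.09 to -0.11 against TMM, which by itself turns calls toward lower. What else differed was not tested. Other planned settings gave 4163 to 5880 genes, and voom with an unadjusted p 5886.

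Acsl1 was positive under each alternative run, from 0.22 to 0.52, and from 0.25 to 0.39 with 1 library left out. With FPKM it was 0.22, 0.22 and 0.22 for the 3 pseudocounts and no longer passed. FPKM moved all genes by a median of -0.10 to -0.11 against TMM. Library totals alone moved them by -0.10 and also gave Acsl1 0.22, but there it passed (edgeR adjusted p = 0.0462). What else ended the call with FPKM was not tested. Runx1 turned to -0.014, -0.015 and -0.015 with FPKM and to -0.0035 with library totals, within its SE of 0 each time. With the most abundant transcript Acsl4 turned to -0.031 and Gpat3 to 0.053, neither past the threshold. Of the 130 named genes 120 to 127 passed with 1 library left out, against 128. Over the named genes other than Acsl1 and all alternatives, 3202 results kept direction and call, 109 lost the call and 3 gained it.

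Between 14 and 17 lists passed camera with 1 library left out, and 0 with an estimated correlation, where the cause was not tested. With the replicate number as a block 4815 genes were called, 2412 higher and 2403 lower, 4248 of them shared with the 4456. Acsl1 stayed past the threshold (0.33, adjusted p = 0.0322), and beyond Nlrc4, the fry result of the Toll-like list and the 4 lists gained by camera (hypoxia, chemokine, NRF2 and stromal genes), the block changed no call of a named gene or of the lists described above. The alternatives for the second phase and for both phases together were not run, since those samples were not analysed here. A gene that did not pass is not shown to be unchanged. In the simulation 1.5-fold changes were recovered for 30 of 50 genes. Far fewer genes were changed there than were called here, so this share does not give the recovery in these data.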

Other observations

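Tests in this part chosen only after the result was seen are the 15 stage lists, both tests of the B-lineage genes, every test of Acsl1, the tests of interferon genes against either neutrophil list and the fry count over splits that part the pairs. Among lists outside the report, hypoxia and HIF1 targets (median 0.28, camera adjusted p = 0.0642, or 0.0201 with the replicate number as a block and 0.880 with the block and an estimated correlation) had the transcription factor Hif1a (200 ± 37.5 against 129 ± 13.5 CPM), the oxidoreductase Ero1a and Ndrg1 higher, and the vasodilator peptide gene Adm lower (0.321 ± 0.208 against 3.15 ± 0.925 CPM). Of 16 chemokine genes 10 passed, 6 of them higher (adjusted p = 0.245, or 0.00866 with the block and 0.763 with the block and an estimated correlation). Ccl2, which draws monocytes, stood at 104 ± 30.6 against 35.5 ± 9.82 CPM, Ccl5 was 2.54-fold and Cxcl10 3.60-fold higher, and the platelet chemokine Pf4 was lower. Of 25 antioxidant genes 16 passed, 11 of them lower (median -0.30; adjusted p = 0.191, or 0.00217 with the block and 0.570 with the block and an estimated correlation). Gclc, the limiting enzyme of glutathione synthesis (52.2 ± 9.98 against 97.5 ± 7.13 CPM), the ferritin chain Fth1 (2473 ± 362 against 4220 ± 785 CPM) and catalase were lower, and the glutathione reductase Gsr was higher (1160 ± 198 against 794 ± 44.4 CPM). Of 30 trained immunity and chromatin genes 10 passed, 6 of them higher (median 0.01; adjusted p = 0.767), with the methyltransferases Dnmt3a and Ezh2 and the kinase Mtor lower by -0.47, -0.45 and -0.35 on the log2 scale. Among all tested genes 34.7% passed, near the share of these 30 genes. The calls of Hif1a (0.76, adjusted p = 0.111), Gclc (-0.72, adjusted p = 0.192) and Dnmt3a (-0.55, adjusted p = 0.0636) ended with the most abundant transcript alone. Removing a smooth trend on GC content and transcript length moved the median of the antioxidant genes from -0.30 to -0.15, that of fatty acid synthesis from 0.11 to 0.21 and that of glycolysis from 0.33 to 0.44. Such moves were not particular to these lists. Trained immunity and chromatin genes moved from 0.01 to 0.12 and macrophage identity markers from 0.31 to 0.41, while chemokines stayed at 0.23.

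Stage lists written after the main results were seen divide the cell lineages further. They hold some genes whose values were already known, such as Akap12, at -4.28 the lowest of the pro-B and pre-B cell genes. Pro-B and pre-B cell genes were lower in 14 of 19 members (median -2.87; summed level 516 ± 140 against 2438 ± 283 CPM), among them Cd79a, the regulator Bach2 and the coreceptor Cd72. Mature B cell genes were lower in 10 of 15 members (median -0.90; 204 ± 54.1 against 819 ± 87.5 CPM), and plasma cell genes had a median of -0.05. Plasmacytoid dendritic cell genes were lower in 6 of 9 members (median -0.75). Late neutrophil genes were higher in 13 of 14 members (median 0.92), with Mmp9 and Ccl6 at 2229 ± 519 and 458 ± 160 CPM in the D libraries, secondary granule genes in 10 of 12 (0.65), and primary granule genes had a median of 0.08. NK cell genes were higher in 8 of 10 members (median 1.71), with Klre1 and the transcription factor Eomes at a mean under 3 CPM in the D libraries (with the most abundant transcript alone the call of Eomes ended; 3.01, adjusted p = 0.0987), and T cell genes in 6 of 13 (0.54). Basophil and eosinophil genes had medians of 0.73 and 0.99, early and late erythroid genes of -0.66 and -0.55, and stem and progenitor cell genes of -0.06. Only 2 of 9 early and 0 of 12 late erythroid genes were called lower, so the late ones are not shown to differ. Monocyte genes were higher in 7 of 14 members (median 0.42), with F13a1 at 345 ± 36.4 against 180 ± 49.6 CPM. The list of monocyte and progenitor markers fixed beforehand had 4 of 17 members higher and 4 lower (median -0.0026, camera adjusted p = 0.671). With an estimated correlation 0 of the 15 stage lists passed (smallest adjusted p = 0.0976).

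For the count of genes the real split had a share under 0.05 over all splits, which speaks against chance only if all splits are equally possible. If the replicate numbers pair the samples, only the splits that part the pairs count. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes changed, the real one with 4456, and the highest of the others was 0; the same held for genes higher and genes lower (1 of 35 each, highest other 0). Among the 8 splits that part all 4 same-numbered pairs, the real one was the 1 with as many genes and the highest other was 0, but 8 splits cannot give a share under 0.05. For the number of lists past camera at its preset correlation chance cannot be excluded: 22 of 35 splits passed 14 or more, the highest other being 22. Why other splits passed so many was not tested. Among the 8 splits that part the pairs 5 passed as many, the highest other being 21, again too few splits for a share under 0.05. With fry, 1 of 35 splits passed 14 lists, a share under 0.05 under the same condition, and the highest other was 1. Among the 8 splits that part the pairs 1 passed as many by fry, the real one, and the highest other was 0, too few splits for a share under 0.05.

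The lower B-lineage genes kept a median between -2.93 and -2.61 over 5 other scalings. These scalings moved the genes by a median of only -0.10 to 0.02 on the log2 scale. The outcome was therefore settled beforehand and is no separate support. Shifts of that size are small beside the list's median of -2.83, so the choice among these scalings does not account for it. Of the tested members 85.7% (12 of 14, Jchain not among them) had a log2 fold change of -1 or below. Fewer B-lineage cells and less transcript in each such cell would both give this, so they cannot be told apart from these values, and diabetes itself stays open and untested as their origin.

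The higher interferon response genes had a median of 1.17 after a smooth trend on GC content and transcript length was removed, against 1.15 before, which argues against that trend, a trend that took 2.57% of the variance of fold changes. More late neutrophils could also raise them, and nothing here excludes that. Interferon genes minus late neutrophil genes differed by 0.193 between groups (exact permutation p = 0.486; D libraries -4.53 to -3.44, M libraries -4.28 to -4.11), and the difference was higher in D in 2 of the 4 same-numbered pairs. Against the neutrophil list fixed beforehand the difference was 0.66 (exact permutation p = 0.0571) and higher in D in 4 of 4 pairs, by 0.06 to 1.22 (exact sign-flip p = 0.125, the smallest that 4 pairs allow). The D libraries spread widely around the M libraries in the first comparison and the pairs are too few in the other, so a response to interferon and a shift in neutrophils cannot be told apart for these genes.

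Acsl1 kept a log2 fold change of at least 0.219 (SE 0.0789) over 5 other scalings, which argues against normalization between libraries as the whole cause. Whether a larger share of late neutrophils raised it stays open. Acsl1 minus the late neutrophil genes differed by -0.68 (exact permutation p = 0.0571, two-sided; lower in D in 4 of 4 pairs, exact sign-flip p = 0.125), and minus the fixed neutrophil list by -0.21 (exact permutation p = 0.0857). Any gene that rose less than the neutrophil genes, or not at all, would give such values, so they support neither answer. A shift in neutrophils and a change of Acsl1 within the macrophages cannot be told apart, and an effect of diabetes within the macrophages was not tested.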
